A study of Clostridium acetobutylicum ATCC 824 with 48 samples.

How the data were processed

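The series holds RNA-seq libraries of Clostridium acetobutylicum ATCC 824. Cultures grew at 37 °C without oxygen in a rich medium with 0.5% xylose, per the labels' protocols. They were split into 70 mL bottles at an OD600 of 0.2, and the addition was made at an OD600 of 0.4. Each bottle received arabinose, glucose or xylose to 0.25% from a 50% stock, or the same volume of water. Samples were taken before the addition (0 min) and 15, 30 and 60 min after it, and rifampicin at 0.03 mg per mL was present at sampling. The 16 groups of addition and time hold 3 libraries each, 48 in all, which the labels call independent biological replicates.

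Ribosomal RNA was depleted before stranded libraries were made and sequenced, per the labels' protocols. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and expression was compared with DESeq2 1.10.1 in R 3.4.0. The settings of the alignment, the genome build, the annotation and the use of strand in counting are not given in the sources used here. The authors deposited 3 kinds of values for the same genes. The deposited counts are whole reads per gene. The deposited RPKM table, used here as a score for one check of the run described in the closing section, holds RPKM values rounded to whole numbers. The deposited rlog table holds regularised log2 values of the counts, and the authors' scaling is part of those values. The files name genes by locus tag only and do not pair tags with names. No annotation was at hand, so the gene lists rest on tags written down from general knowledge before the data were examined.

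The count table holds 3778 genes, of which 3602 carry a chromosomal tag and 176 a tag of the megaplasmid pSOL1. It has no ribosomal or transfer RNA genes. Library totals ran from 4898030 to 23397755 counts, and no library had more than 28 genes at 0. Counting error is therefore small beside the spread between replicates for all but the weakest genes. After edgeR's filterByExpr by group, 3749 genes were tested and 29 were left out.

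Counts were scaled by TMM and fitted with edgeR 4.0.16 (quasi-likelihood) in R 4.3.3, with 1 mean per group over all 48 libraries. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and calls of at least 2-fold were also counted. The 19 comparisons were each sugar against water at 15, 30 and 60 min, each sugar's bottles against the water bottles at 0 min, arabinose against glucose, arabinose against xylose, and water at 60 min against 0 min. The difference between a sugar's effects at 60 and 15 min was tested as an interaction in the same fit. CPM values use the TMM-scaled library sizes, and their log2 values have a prior count of 2.

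Of 21 gene lists, 19 could be tested, and 2 lists (ribosomal proteins, motility and chemotaxis) depended on product names and had no members. The xylan and arabinan list and the sporulation list were to be extended by product name and were tested with their tags alone. Lists were tested with limma 3.58.1 (fry, on voom values of the same fit), adjusted over the 171 tests of the 9 sugar comparisons with water, and separately for the other kinds of comparison. The fry test asks whether the members move one way on balance and does not compare a list with other genes. In the list of other sugar PTS operons, 3 tags were entered with the wrong replicon (CA_C0066 to CA_C0068 where CA_P0066 to CA_P0068 were meant), and the list was tested as entered.

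Genes named in the text follow a rule set before the data were examined. It takes the members of the arabinose, xylose, phosphoketolase and catabolite repression lists, up to 4 members of other called lists, and the 5 rising and 5 falling genes with the largest change per comparison. The last of these needed a mean count of at least 20 and no overlap between the groups' libraries, and at most 2 of them per direction are printed where no list holds them. CA_P0066 to CA_P0068, runs of neighbouring tags, CA_C0919, CA_C1353, CA_C2703, CA_C2963 to CA_C2966 and CA_C3714, and CA_C2956 to CA_C2958 at 30 min, were chosen after their values were seen.

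Alternatives covered DESeq2 1.42.0, limma on the deposited rlog values, size factors and upper-quartile factors in place of TMM, no filter and a stricter filter (50 counts in 3 libraries), a fit of only the libraries compared, a difference to the 0 min samples, a block by replicate number, each library left out in turn, and camera with a preset correlation of 0.01 and with an estimated one. The difference to the 0 min samples was also fitted with a block by assumed bottle. It takes libraries of the same addition and replicate number as the same bottle, which no label states. A covariate for an axis of spread and changes to the PTS list were added after the data were examined. Same-numbered libraries were checked for shared deviations. Over the 72 pairs from different sugars at the same time the mean correlation of their deviations from the group means was 0.02, and over 72 pairs of the same sugar at different times it was 0.0169. Only for xylose and water at 30 min did every same-numbered pair exceed 0.1, with values of 0.207, 0.106 and 0.112. At the same time, 22 of the 72 same-numbered pairs exceeded 0.1, as did 38 of 144 pairs with different numbers. The values at 30 min therefore establish no pairing, and the labels name no shared batch or day.

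The procedures were tested on simulated counts with 200 changed genes in the arabinose 15 min libraries. In arabinose against water at 15 min, over 3745 simulated genes, edgeR recovered 85% of the genes changed 1.5-fold and 98% of those changed 2-fold, with 10 false calls. For the difference between 60 and 15 min it recovered 55% and 95%, with 8 false calls. Each gene was drawn independently, so spread shared between genes is absent, and these rates need not hold for the real libraries. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.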

Results

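Gene expression was measured by RNA-seq in Clostridium acetobutylicum cultures that grew on xylose and then received arabinose, glucose, more xylose or water. The 48 libraries form 16 groups of 3, with 4 additions sampled at 0, 15, 30 and 60 min. Totals ran from 4898030 to 23397755 counts per library. The study's title asks how arabinose affects the use of other sugars in this organism, so arabinose is compared below with water, glucose and xylose. Functions attached to tags come from gene lists fixed in advance, because the deposited tables give tags without names. Log2 fold changes are given with their standard errors, and all adjusted p-values of single genes are from edgeR's quasi-likelihood test with n = 3 per group. For lists, adjusted p-values given with an estimated correlation are from camera, which compares a list with the other genes. A list call by fry that is lost there does not show that the list's members were unchanged.

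The first 2 principal components held 45.7% and 17.2% of the variance of log2 CPM. Glucose libraries lay apart from water libraries at 15 min, and arabinose libraries moved in the same direction along the first component at 30 and 60 min. Before any addition, none of the 3749 genes was called between the bottles meant for a sugar and those meant for water with edgeR. At an unadjusted p under 0.05 there were 104 genes for arabinose, 226 for glucose and 97 for xylose. DESeq2 called 10 genes for glucose and 0 for the others, and limma on the deposited rlog values 0 for each sugar. A fit of only the 6 libraries called 43 genes for glucose, all down, and 0 for arabinose and xylose (362 and 238 at an unadjusted p under 0.05). With a covariate for an axis of spread 3 were called for glucose.

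**Figure D1:**
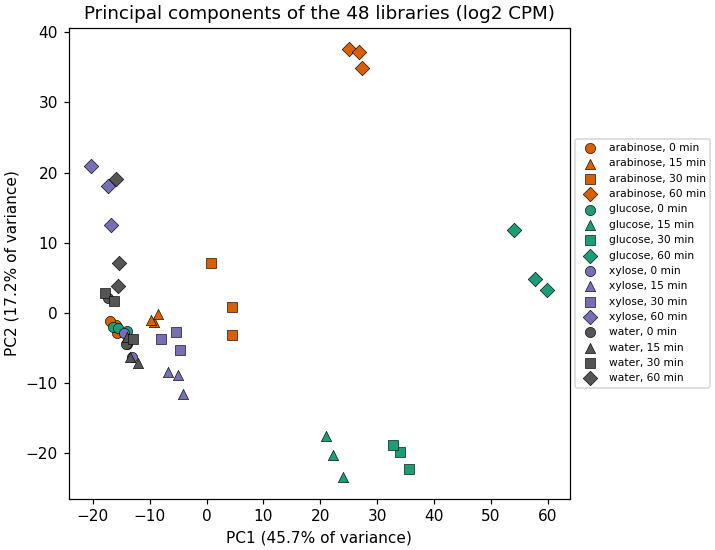
Principal components of log2 CPM, with the 1st component on the x axis and the 2nd on the y axis, 1 point per library. Colours give the addition and shapes the time; the 3 arabinose and 3 glucose libraries at 60 min lie farthest from the libraries taken at 0 min.

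Arabinose raised its own uptake and catabolism genes within 15 min. All 7 members of that list rose, with a median log2 fold change of 3.39 (fry adjusted p 5.83e-28, Up), and the same 7 were called when adjusted over the list alone. Among them CA_C1341 rose by 3.63 ± 0.11, CA_C1349 by 3.47 ± 0.11 and CA_C1346 by 3.39 ± 0.11. The largest change was in CA_C1343 of the phosphoketolase and pentose phosphate list, from 107 ± 11.8 CPM with water to 24100 ± 1320 with arabinose (SD, n = 3), a log2 fold change of 7.81 ± 0.17 (adjusted p 1.46e-32). Its list neighbours CA_C1347 and CA_C1348 rose by 3.14 ± 0.15 and 3.36 ± 0.11. The 3 genes of the galactose list rose together, with a median of 1.06. Among genes outside the lists, CA_C1660 and CA_C1406 fell most, by 2.52 ± 0.11 and 2.30 ± 0.12 log2 units. In all, 655 genes were called at 15 min, 271 up and 384 down, of which 51 and 48 changed at least 2-fold (436 without arabinose 15 min replicate 1). A fit of only the 6 libraries called 1076 (526 up, 550 down), and the difference to the 0 min samples 371, or 379 with a block by assumed bottle. The balance of rising and falling genes has no fixed direction, since RLE size factors gave 326 up and 319 down and DESeq2 341 and 338.

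Most genes of xylose use fell further with arabinose after 15 min. At 15 min the 8 members of the xylose list had a median of -0.38 and the list was not called by fry (adjusted p 0.117), though camera with a preset correlation called it Down (adjusted p 0.0405, and 0.383 with an estimated correlation), with 5 members down (6 adjusted over the list alone) and CA_C1345 up by 2.95 ± 0.12. At 30 min 7 of the 8 were called down with a median of -2.37 (fry adjusted p 1.03e-23), and at 60 min all 8 with a median of -3.35 (fry adjusted p 3.71e-29), with 7 and 8 down when adjusted over the list alone. CA_C3451 and CA_C3452 fell by 4.79 ± 0.12 and 4.63 ± 0.13 at 60 min, and CA_C2610 fell by 4.19 ± 0.12, from 4990 ± 563 CPM with water to 273 ± 20.4 with arabinose. The difference between the effects at 60 and 15 min, tested as an interaction, had a median of -3.46 in this list.

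**Figure D2:**
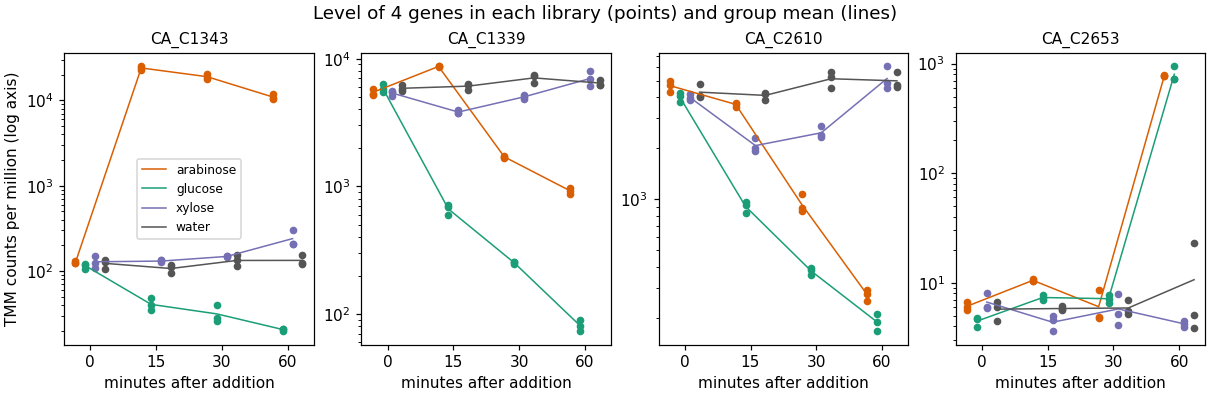
TMM CPM on a log axis against minutes after addition, for CA_C1343, CA_C1339, CA_C2610 and CA_C2653. Points are libraries and lines join group means; CA_C1343 reaches 24100 with arabinose at 15 min against 107 with water.

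The arabinose genes themselves did not keep their early rise as a group. At 60 min 4 of the 7 were up and 3 were down, with CA_C1339 at -2.80 ± 0.09, CA_C1349 at -1.80 ± 0.10 and CA_C1346 at -1.10 ± 0.11. The list's median was then 1.09, its mean -0.06, and fry called it Down at an adjusted p of 0.048 (adjusted p = 0.963 with an estimated correlation), so median and test differ in sign. That call was lost without arabinose 60 min replicate 2 (adjusted p 0.0917) or water 60 min replicate 1 (0.353). CA_C1343 stayed high at 30 and 60 min, at 7.16 ± 0.17 and 6.37 ± 0.16. The phosphoketolase and pentose phosphate list had a median of -0.16 and a mean of 0.56 at 60 min, where fry called it Up (adjusted p 1.43e-05, and 0.986 with an estimated correlation), another case in which median and test differ in sign. That median was -0.29 and -0.09 without arabinose 60 min replicates 1 and 3 and -0.03 without water 60 min replicate 1.

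Transport genes for other sugars and part of the catabolite repression list moved with arabinose too. Of the 5 genes in the latter list 3, 4 and 3 were down at 15, 30 and 60 min, and its call at 60 min was lost with an estimated correlation (adjusted p = 0.25). In it CA_C3087 fell by 1.23 ± 0.13 at 15 min, 3.56 ± 0.14 at 30 min and 3.68 ± 0.14 at 60 min, and CA_C3037 and CA_C0570 fell at each time, while CA_C1820 rose by 0.54 ± 0.17 at 60 min. The list of other sugar PTS operons, which holds 3 tags entered with the wrong replicon, had 17, 24 and 29 of 32 members down (19, 24 and 29 adjusted over the list alone), with medians of -0.45, -1.71 and -1.58. Members up numbered 7, 4 and 0. At 15 min these were CA_C2956, CA_C2957 and CA_C2958, by 2.52 ± 0.10, 2.52 ± 0.13 and 2.29 ± 0.18, and CA_C2963 to CA_C2966, by 0.60 to 0.99. CA_C2956 to CA_C2958 were still up at 30 min by 0.43 to 1.30, as was CA_C1353 by 0.75 ± 0.10. The galactose genes turned from a rise at 15 min to medians of -1.15 and -0.80 at 30 and 60 min, calls that were lost with an estimated correlation (adjusted p = 0.0661 and 0.275). Counts of called genes grew to 1718 (875 up, 843 down) at 30 min and 2366 (1145 up, 1221 down) at 60 min, where RLE size factors turned the balance to 1192 up and 1180 down.

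Purine and pyrimidine genes had their largest list medians at 30 and 60 min, respectively, with arabinose. The 7 purine genes rose at 30 min with a median of 1.54 (fry adjusted p 3.32e-18) and lay below water at 60 min with a median of -1.30 (fry adjusted p 2.74e-15, and adjusted p = 0.16 with an estimated correlation). The 7 pyrimidine genes had a median of 0.92 at 15 min with 6 called up (7 adjusted over the list alone, fry adjusted p 0.00105, and adjusted p = 0.235 with an estimated correlation). None was called at 30 min, with a median of 0.11 (fry adjusted p 0.588), and all rose at 60 min by a median of 5.98 (fry adjusted p 1.2e-23, and adjusted p = 0.0551 with an estimated correlation). CA_C2653 reached 781 ± 6.57 CPM against 10.7 ± 10.7 with water. In this list water 60 min replicate 1 lay above the other 2 water libraries, with 102 against 5.52 CPM for CA_C2645.

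Glucose lowered both pentose lists at every time. The arabinose list had medians of -2.64, -3.65 and -3.69 at 15, 30 and 60 min, and CA_C1339 fell by 6.31 ± 0.10 at 60 min, from 6440 ± 304 to 81.2 ± 8.33 CPM (adjusted p 1.3e-37). The xylose list had medians of -2.14, -3.49 and -4.15 with all 8 members down at each time, also when adjusted over the list alone. CA_C1343 fell by 1.40 ± 0.14, 2.09 ± 0.15 and 2.69 ± 0.15. The galactose list followed with medians of -2.27, -2.54 and -2.94, calls lost with an estimated correlation (adjusted p = 0.0566, 0.0551 and 0.125). The list of other sugar PTS operons had medians of -2.14, -2.30 and -2.15, with 28, 27 and 27 members down and 3, 4 and 4 up, its 3 misentered tags among those up. In the catabolite repression list CA_C3087 fell by 5.23 ± 0.15 at 60 min and CA_C3037 by 2.31 ± 0.08, while CA_C1089 rose by 0.45 ± 0.11. The list's call at that time was lost with an estimated correlation (adjusted p = 0.0852).

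Rising genes with glucose included the sulfate and cysteine list, with all 9 members up at 15 min by a median of 2.12 (fry adjusted p 4.62e-09) and a median of 0.96 at 60 min. Both calls were lost with an estimated correlation (adjusted p = 0.25 and 0.824). The purine list rose by medians of 0.84, 1.91 and 1.96 (adjusted p = 0.192, 0.0566 and 0.132 with an estimated correlation, so no longer called). For the pyrimidine list the medians were 0.33, 0.32 and 6.0, the first and second of these not called (fry adjusted p 0.24 and 0.376) and the last called by fry but not with an estimated correlation (adjusted p = 0.112). Outside the lists, CA_C3514 and CA_C3513 rose most at 15 min, by 4.49 ± 0.12 and 3.58 ± 0.10, and CA_C3670 and CA_C3672 fell most, by 4.9 ± 0.13 and 4.66 ± 0.11. Called genes numbered 2088 (1048 up, 1040 down), 2400 (1337 up, 1063 down) and 2746 (1449 up, 1297 down) at the 3 times. With DESeq2 the splits were 1005 and 1076, 1202 and 1206, and 1360 and 1362, so the balance over all calls has no fixed direction either. Calls of at least 2-fold with edgeR numbered 241 up and 213 down, 457 and 296, and 644 and 416.

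**Figure D3:**
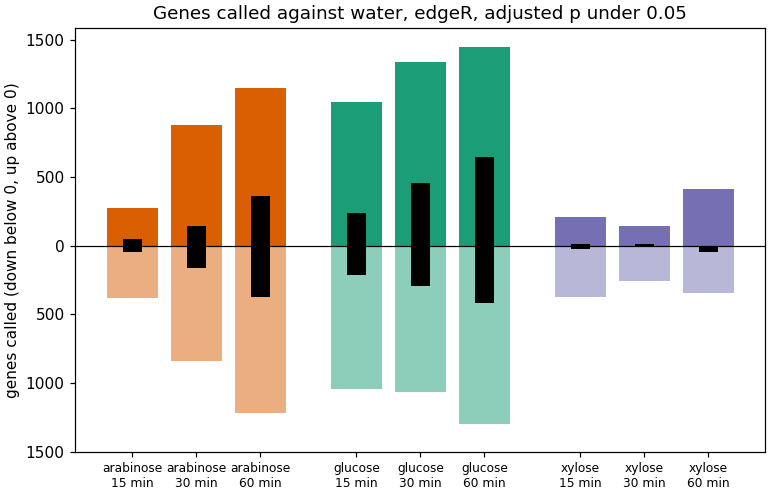
Genes called against water for each sugar and time, with genes up above 0 and genes down below 0 on the y axis. Wide bars show all called genes and black bars those of at least 2-fold. Glucose at 60 min has 1449 up and 1297 down, and xylose at 30 min 140 up and 259 down, a balance that upper-quartile factors turned round.

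Added xylose lowered the xylose genes for a time. Its list had medians of -0.86 at 15 min with all 8 members down (fry adjusted p 2.69e-13), -0.98 at 30 min (4.39e-12) and -0.07 at 60 min (0.74). CA_C2612 fell by 1.25 ± 0.09 at 15 min and CA_C2610 by 1.06 ± 0.11 at 30 min. The list of other sugar PTS operons, with its 3 misentered tags, had 26 of 32 members down at 15 min (27 adjusted over the list alone, median -0.71). The ATP synthase genes rose at 15 min by a median of 0.70, all 9 up, and the purine list had medians of 0.39, 0.66 and 0.42 at the 3 times, with 4, 7 and 6 of 7 members up (6, 7 and 7 adjusted over the list alone). With an estimated correlation the purine calls at 15 and 60 min were lost (adjusted p = 0.114 and 0.0551). Outside the lists, CA_C2752 and CA_C0844 rose most at 15 min, by 1.67 ± 0.09 and 1.65 ± 0.08.

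Against water, 581 genes were called with xylose at 15 min, 399 at 30 min and 755 at 60 min, with 34, 17 and 48 of them changed at least 2-fold. Of these large changes 12, 9 and 0 were up and 22, 8 and 48 down. The 5 falling genes named by the rule at 60 min were weak, at 2.12 to 8.9 CPM with xylose. Xylose 60 min replicate 2 had the lowest TMM factor (0.75) and the most genes at 0 (28) of all libraries. Whether library quality lies behind the falls was not tested. At 15 min the count of all called genes was 384 without water replicate 2, 336 without xylose replicate 2 and 360 without xylose replicate 3. At 30 min it was 212 without water replicate 1 and 242 and 263 without xylose replicates 2 and 3. At 60 min it was 1236, 200 and 228 without water replicates 1, 2 and 3 and 94 without xylose replicate 2, and a fit of only those 6 libraries called 0 genes (463 at an unadjusted p under 0.05). As differences to the 0 min samples the counts were 198, 91 and 313 (206, 83 and 276 with a block by assumed bottle), and with a covariate for an axis of spread 283 at 60 min. At 60 min CA_C1343 rose by 0.85 ± 0.13 with xylose, and the arabinose list was called up with a median of 0.45 and 5 of 7 members up (6 adjusted over the list alone, fry adjusted p 2.5e-06, and adjusted p = 0.0551 with an estimated correlation).

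Genes of ATP synthase, heat shock and the cellulosome also moved with arabinose and glucose. ATP synthase genes had medians of 0.59, 0.61 and 0.66 with glucose and 0.09, 0.52 and 0.59 with arabinose, with 9, 8 (9 adjusted over the list alone) and 7 and then 1, 8 and 6 of 9 members up, the 1st arabinose value not called (fry adjusted p 0.371). The other 5 calls were lost with an estimated correlation (adjusted p = 0.402, 0.467 and 0.595 with glucose, 0.378 and 0.627 with arabinose), and the last median was 0.38 without arabinose 60 min replicate 1. Of 12 heat shock and chaperone genes 8 were up with arabinose (9 adjusted over the list alone) and 7 with glucose at 60 min, with medians of 0.56 and 0.80, while CA_C3714 fell by 0.45 ± 0.14 and 0.66 ± 0.14. Of 12 cellulosome genes 11 and 10 were down, with medians of -1.08 and -0.67, and CA_C0919 rose by 0.84 ± 0.15 with glucose. With an estimated correlation all 4 calls were lost (adjusted p = 0.598 and 0.579, then 0.397 and 0.666). At 30 min the heat shock list was called with arabinose at a median of -0.20 (fry adjusted p 0.0219). That call was lost with an estimated correlation (adjusted p = 0.78). With glucose the list was not called at 15 or 30 min (fry adjusted p 0.431 and 0.779). Its median with arabinose at 60 min was 0.33 without arabinose 60 min replicate 1. That library stood apart from replicates 2 and 3 (chi-square per degree of freedom 58.5 and 69.8, against 15.1 between the other 2), and CA_C2703 had 7227 ± 2950 CPM with arabinose against 4498 ± 861 with water.

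Xylan and arabinan genes went both ways with arabinose at 15 min. Of 14 members 5 were up, led by CA_C1529, CA_C1530 and CA_C1531 at 3.13 ± 0.16, 2.91 ± 0.12 and 2.88 ± 0.13, and 2 were down. Fry called the list Up (adjusted p 1.57e-11, and 0.113 with an estimated correlation), with a median of 0.05 that has no fixed sign (-0.02 without water 15 min replicate 2, 0.11 without water 15 min replicate 1). At 30 and 60 min the medians were -0.07, not called (fry adjusted p 0.836), and -0.63 (adjusted p = 0.402 with an estimated correlation). With glucose they were -0.68, -0.95 and -0.89, with calls lost likewise (adjusted p = 0.0791, 0.0701 and 0.0852). The sulfate and cysteine list was called with arabinose only at 60 min (median 1.23, fry adjusted p 0.0209, and adjusted p = 0.824 with an estimated correlation), and not without arabinose 60 min replicate 1 (adjusted p 0.335) or water 60 min replicate 3 (0.131). Glycogen genes had a median of -0.56 with glucose at 60 min, all 5 down, and sporulation genes -0.39, -0.35 and -0.43 with glucose over the 3 times, with 4, 4 and 3 of 4 down. Fry called all 4, and none was called with an estimated correlation (adjusted p = 0.383, then 0.235, 0.322 and 0.378). The glycolysis list had medians of -0.03 with arabinose (up to 0.01 with upper-quartile factors or a stricter filter, so of no fixed sign) and -0.31 with glucose at 60 min, neither called (fry adjusted p 0.524 and 0.835). The solvent list stood at 0.02 and 0.15, also not called (0.867 and 0.624, with fry's direction opposite to both medians and to that of glycolysis with glucose). For acid formation the medians were 0.15 and 0.25, the second called at 0.0461 but not without glucose replicate 1 (0.149) or 3 (0.0581) or water replicate 2 (0.278) or 3 (0.203), nor with an estimated correlation (adjusted p = 0.963). The 175 megaplasmid genes had a median of -0.15 with arabinose at 60 min (-0.09 without arabinose replicate 1 or water replicate 3), called by fry (adjusted p 2.97e-05) but not with an estimated correlation (adjusted p = 0.899).

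**Figure D4:**
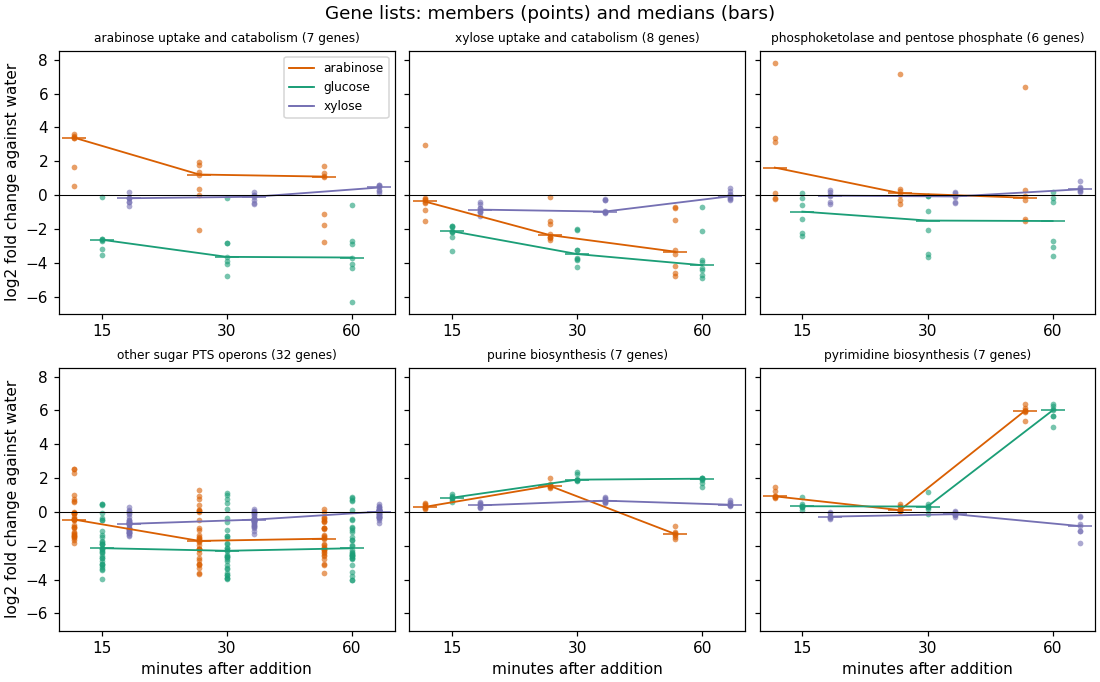
Log2 fold change against water for the members of 6 gene lists at 15, 30 and 60 min, with points for genes, horizontal bars for list medians and lines joining them. The pyrimidine medians reach 5.98 with arabinose and 6.0 with glucose at 60 min.

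Set side by side at the same time, arabinose and glucose left different levels of the pentose genes. The arabinose list was higher with arabinose by medians of 6.05, 4.02 and 3.51 at 15, 30 and 60 min, all 7 members up each time. For the xylose list the medians were 1.68, 1.03 and 0.51, with 8, 8 and 6 of its 8 genes higher with arabinose, and the call at 60 min was lost with an estimated correlation (adjusted p = 0.29). CA_C1343 was higher with arabinose by 9.25 ± 0.19 at 30 min. The sulfate and cysteine genes were lower with arabinose at 15 min (median -1.80, adjusted p = 0.247 with an estimated correlation), and purine genes at 60 min (median -3.18). Called genes numbered 1910, 2074 (1371 with a covariate for an axis of spread) and 2261.

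Many genes were called in the same direction with arabinose and with glucose. There were 447 at 15 min, 1235 at 30 min and 1711 at 60 min, which is 86.3%, 91.3% and 88.5% of the genes called with both. Independent lists of these sizes would share 75.8 up and 107 down at 15 min, 312 and 239 at 30 min, and 443 and 422 at 60 min. Over genes, which are not independent replicates, log2 fold changes correlated at 0.286, 0.598 and 0.664, and their covariances were 0.0919, 0.367 and 0.788. Both comparisons use the same water libraries. Unchanged groups and the water group they share were simulated from the water means, with independent noise for each gene. In these draws on average 0.05, 0.1 and 0.15 genes were called in the same direction, and at most 1 at each time. Their mean correlation was 0.489, 0.546 and 0.514. It comes from noise in the shared water group alone, so it is no bound for groups that changed. The observed correlation lay below all simulated ones at 15 min (lowest 0.439), within them at 30 min (highest 0.609) and above them at 60 min (highest 0.554). Simulated covariances were 0.0134, 0.0207 and 0.0169, which leaves differences in covariance of 0.0785, 0.346 and 0.771. Spread shared between genes is absent from these draws. Glucose against xylose, which shares no library with arabinose against water, gave 392, 1147 and 1680 genes in the same direction.

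Arabinose and added xylose, both pentoses at the same dose, differed in 665, 1683 and 2567 genes at 15, 30 and 60 min, the first of them 1066 in a fit of only the 6 libraries. The arabinose list was higher with arabinose at 15 min by a median of 3.64, with all 7 members up. At 30 min CA_C1343 was higher with arabinose by 7.00 ± 0.17, CA_C3087 was lower by -3.33 ± 0.14 and CA_C3670 by -3.34 ± 0.12.

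Water cultures drifted over the hour. Between 0 and 60 min 1078 genes were called, 565 up and 513 down, and 59 and 33 of these changed at least 2-fold (502 up and 584 down with upper-quartile factors). A fit of only the 6 libraries called 600, 254 up and 346 down. Every comparison with water above is made at the same time, so drift that the sugar cultures share cancels. Drift in the water cultures alone would stay part of those values, and how much was shared was not tested.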

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

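The splits of the libraries, the tests of the pyrimidine rise, the test of exchanged labels and that of a single library behind the run of neighbouring tags were chosen after the result was seen. The counts and list medians of the 60 minus 15 min differences, among them the pyrimidine rise, were picked out by a test of that difference. Xylose at 60 min and the run of neighbouring tags were taken up after their values were seen.

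The arabinose effect differed in 1921 genes, the glucose effect in 1849 and the xylose effect in 686. The xylose count was 448 without xylose 15 min replicate 2, 271 without xylose 60 min replicate 2, and 1109 and 265 without water 60 min replicates 1 and 3, and it was 119 in a fit of only the libraries compared and 232 with a covariate for an axis of spread. With arabinose, the list medians of the difference were -2.21 for arabinose genes, -3.46 for xylose genes, -0.79 for the phosphoketolase list, -1.09 for xylan and arabinan genes, -0.21 for catabolite repression, -1.34 for other sugar PTS operons (3 tags misentered), -1.93 for galactose, -0.97 for the cellulosome, -1.64 for purine and -0.14 for megaplasmid genes. Positive differences were 5.06 for pyrimidine genes, 0.70 for heat shock and 0.38 for ATP synthase. With an estimated correlation only the arabinose, xylose and PTS lists were still called, and adjusted p ran from 0.0524 to 0.751 in the others.

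With glucose the medians were -0.75 for arabinose genes, -1.62 for xylose genes, -0.32 for the phosphoketolase list, -0.36 for xylan and arabinan genes, -0.054 for catabolite repression, -0.27 for galactose, -0.32 for glycogen, -1.08 for sulfate and cysteine and -0.15 for megaplasmid genes. Heat shock differed by 0.47, purine by 0.98 and pyrimidine by 5.52. None of these lists was called with an estimated correlation (adjusted p from 0.0524 to 0.73). With xylose they were 0.77 for arabinose genes, 0.76 for xylose genes, 0.45 for the phosphoketolase list, 0.25 for xylan and arabinan genes, 0.41 for catabolite repression, 0.75 for other sugar PTS operons, 0.38 for galactose, 0.35 for acid formation and 0.32 for solvent formation. The arabinose, xylose and PTS lists were still called with an estimated correlation, and adjusted p ran from 0.167 to 0.619 in the others.

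For these differences 33 splits of the 12 libraries were drawn, and the share of splits as large excludes chance for none of the 3 sugars. As many genes came from 2 splits for arabinose (1921, highest other 1945), 4 for glucose (1849, highest other 2373) and 2 for xylose (686, highest other 795), the real one included. In arabinose and glucose the other splits as large (1 and 3) kept the true grouping at 1 of the times, and so kept that time's effect. Whether sugar and water were mixed or exchanged whole at the other time was not recorded. Splits that mixed the libraries at both times called at most 7 genes for arabinose and 0 for glucose with edgeR, a reading made after the counts were seen. In xylose the other split as large, with 795, was of that kind.

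For 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest other were 655 and 0, 1718 and 0, and 2366 and 551 for arabinose against water at 15, 30 and 60 min. For glucose they were 2088 and 0, 2400 and 1, and 2746 and 72, and for xylose 581 and 0, 399 and 0, and 755 and 1176. Arabinose against glucose gave 1910 and 0, 2074 and 0, and 2261 and 103, arabinose against xylose 665 and 1, 1683 and 1, and 2567 and 626, and water over time 1078 and 49. In each of these 1 split, the real one, was as large, except for xylose at 60 min with 3. At 0 min all 10 splits gave 0 genes with edgeR for arabinose, glucose and xylose (104, 226 and 97 in the real split at an unadjusted p under 0.05; DESeq2 called 10 for glucose).

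The pyrimidine list rose by 5.98 with arabinose and 6.0 with glucose at 60 min (adjusted p = 0.0551 and 0.112 with an estimated correlation). No single library carried it, since the lowest median with any 1 of the 9 libraries left out was 5.57 (5.565 before rounding), nor did scaling, whose lowest median over RLE, upper-quartile and DESeq2 was 5.89. Its size does depend on water 60 min replicate 1. That library lay higher in these genes (CA_C2645 at 102 CPM against a mean of 5.52 in replicates 2 and 3), which lowers the medians given. Every arabinose and glucose library at 60 min had a mean log2 CPM over the list of 10.57 or more. The highest value at 60 min was 5.961 with water (replicate 1) and 4.339 with xylose, and no library at 0 min exceeded 3.959. The rise thus came with the addition of arabinose or glucose, and its mechanism is not decided by any test here. Water 60 min replicate 1 also stood above the other water libraries in these genes, by a median of 2.39% of the arabinose and 2.74% of the glucose signal. Whether reads from such a library were mixed in cannot be told apart from a change in that culture, because only 1 gene marks arabinose alone (share 0.315%) and the quartiles of the 118 glucose markers (median 1.3%, from -1.39% to 3.77%) overlap those of the pyrimidine genes (2.21% to 3.34%).

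Xylose against water at 60 min was the comparison in which a split with water replicate 1 among the xylose libraries called more genes (1176) than the real one (755), which points to a structure of the samples. An axis taken from the 42 libraries of the other groups held 26.2% of their within-group variance. Over those libraries it correlated at -0.794 with the within-group log2 TMM factor. On this axis the xylose 60 min libraries scored 13 to 18.1 and water 60 min replicate 1 scored 16.6. Water 60 min replicates 2 and 3 scored 5.48 and 1.35. With the axis as a covariate 283 genes were called, 243 of them among the 755. That lay between the bounds set beforehand for this axis as the whole source and for no part in it, so its share stays open. If water replicate 1 and xylose replicate 3 had been exchanged, they would lie on the other group's side in 214 genes called with xylose at 15 and 30 min. Water replicate 1 lay at -0.0656 and xylose replicate 3 at 0.0555 from the midpoint, each on its own side but within 2 replicate SDs (1 SD 0.039), so this too cannot be told apart.

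A run of 65 neighbouring tags, CA_C1161 to CA_C1227, rose with glucose at 60 min by a median of 3.86. The nearby run CA_C1139 to CA_C1159 (19 tags) rose by a median of 5.02. With arabinose at 60 min CA_C1161 to CA_C1168 (8 tags) rose by a median of 2.01, and of all 65 tags 14 were called up and 9 down. The summed level of the 65 tags was 8460 ± 1610 CPM with glucose against 1070 ± 79.6 with water (SD, n = 3). At 0 min it was 1030 ± 25.9 in the glucose bottles and 1050 ± 92.2 in the water bottles. With glucose 24 of the 65 tags were called up and 3 down at 15 min (median 0.35), and 58 up and 0 down at 30 min (median 1.30). With xylose 1, 0 and 0 were called up at 15, 30 and 60 min. With any 1 of the 6 libraries left out the median was at least 3.67 (3.669 before rounding). Extra DNA of the region in the libraries would add similar RPKM to each gene, but the 90th percentile of the added RPKM was 7.01 times the 10th. The rise followed the addition of glucose, but its mechanism was not tested. More copies of the region with more transcription may remain, as no DNA was measured.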

How the results depend on the processing

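The covariate for an axis of spread, the changes to the PTS list, the leave-one-out of lists and all alternatives of the 60 minus 15 min differences were chosen after the data were seen, the others before. Unless a value below shows its cause by fewer libraries or a stricter bound, the cause was not tested.

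Of 727 values of 154 named genes 646 were called. DESeq2 left 720 on their side of the threshold with their direction, the replicate block 725, limma on the deposited rlog 715, RLE size factors 720, upper-quartile factors 709, no filter 716, a stricter filter 715 (1 value missing) and the 6-library fits 661, none with a reversed sign. The difference to 0 min left 485, 71 weaker and 1 stronger (486 and 71 by assumed bottle). With each library left out 4170 stayed, 175 were weaker, 17 stronger and none reversed. The covariate left 674 and reversed 6, all in CA_C1730: 0.37 for glucose at 30 min (main -0.04) and 0.38 at 60 min (main -0.18), 0.064 for arabinose at 60 min (main -0.28), -0.26 and -0.10 for arabinose against glucose at 15 and 30 min (main 0.02 and 0.38), and 0.084 for arabinose against xylose at 60 min (main -0.48).

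Fits of only the libraries compared, with fewer samples behind the spread, called 1076 genes for arabinose against water at 15 min (655 in the fit of all libraries), 1066 for arabinose against xylose at 15 min (665), 600 for water at 60 against 0 min (1078), 43 for glucose at 0 min (0), 119 for the xylose 60 minus 15 min difference (686), and 0 for xylose at 60 min (755; 463 at an unadjusted p under 0.05). DESeq2 called 10 for glucose at 0 min. As a difference to the 0 min samples, which adds their error, 371 were called for arabinose at 15 min and 198, 91 and 313 for xylose at 15, 30 and 60 min (581, 399 and 755). With the covariate, xylose at 60 min gave 283, its 60 minus 15 min difference 232, arabinose against glucose at 30 min 1371 (2074) and glucose at 0 min 3.

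A replicate block changed no count of genes by over 1.5 times. Xylose at 30 min gave 443 with it against 399. With a block by assumed bottle, the difference to 0 min gave 379 for arabinose at 15 min and 206, 83 and 276 for xylose at the 3 times. That block rests on the replicate numbers, which no label ties to bottles. A block in fry ended 1 list call, acid formation with glucose at 60 min, and added 1, glycogen with xylose at 15 min.

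With each library left out, counts ran from 436 (without arabinose 15 min replicate 1) to 591 for arabinose at 15 min, 336 (without xylose replicate 2) to 594 for xylose at 15 min, 212 (without water replicate 1) to 509 at 30 min, 94 (without xylose replicate 2) to 1236 (without water replicate 1) at 60 min, and 265 (without water 60 min replicate 3) to 1109 (without water 60 min replicate 1) for the xylose 60 minus 15 min difference. No other count moved by over 1.5 times.

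Of 171 list values 107 were called by fry. With an estimated correlation camera called 5 lists for arabinose at 15 min (9 by fry), 4 at 30 min (11) and 2 at 60 min (14). For glucose it called 4, 4 and 3 (14, 14 and 16). For xylose it called 3, 3 and 0 (8, 10 and 11). Camera, unlike fry, compares a list with other genes. PTS was called in 8 of the 9 comparisons and the xylose list in 7. With the preset correlation 7 and 5 lists were called for arabinose at 30 and 60 min and 10 for glucose at 60 min. At 60 min with arabinose, the arabinose list (median 1.09) and the phosphoketolase list (median -0.16) had opposite directions under fry and camera, with camera p of 0.797 and 0.946 preset and 0.963 and 0.986 estimated. Correcting or leaving out the 3 wrong PTS tags changed no call. Other scalings and filters changed the sign of 13 list medians, none in a called list.

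Upper-quartile factors moved the split of calls up and down for xylose to 334 and 276 at 15 min (210 and 371), 266 and 205 at 30 min (140 and 259), 314 and 422 at 60 min (411 and 344) and 248 and 439 for the 60 minus 15 min difference (417 and 269), whose median over all genes went from 0.0514 to -0.0596. Filters moved arabinose at 15 min to 336 and 310 (no filter) or 344 and 309 (stricter), from 271 and 384, and arabinose against glucose at 30 min to 1270 and 880 or 1261 and 861, from 1019 and 1055. Genes shared by arabinose and glucose at 2-fold or more were 50, 221 and 499, since that bound drops small changes (447, 1235 and 1711). Leaving out ribosomal and transfer RNA gave no value, as the table has none. Depth (4898030 counts or more) limits the weakest genes.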

Other observations

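The megaplasmid test, and those of a delay for 30 and 60 min apart with libraries left out, were chosen after the result was seen; the first test of a delay and that of shuffled gene orders were set before.

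The share of counts on megaplasmid genes fell from 4.85% ± 0.306 with water to 1.68% ± 0.131 with arabinose and 2.04% ± 0.0805 with glucose at 60 min (SD, n = 3). Loss of the plasmid could lower all its genes alike, but the lower of the 2 medians over 175 tags was -0.153 on the log2 scale, and the quartiles with arabinose were -0.553 and 0.379. Without CA_P0066 to CA_P0068 the shares were 1.62%, 1.48% and 1.90%. These 3 tags, singled out after their values were seen, fell by 4.08 to 4.12 with arabinose and by 4.32 to 4.96 with glucose.

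Arabinose called fewer genes than glucose at 15 min, and its response might be that of glucose with a delay. Arabinose against water was correlated over genes, which are not independent replicates, with glucose against xylose, so that no library was shared. Arabinose at 60 min correlated with glucose at 60 min at 0.627 and at 30 min at 0.419, a difference of -0.208, and arabinose at 30 min with glucose at 30 min at 0.56 and at 15 min at 0.511. A delay of the whole gap between sampling times would give the higher value to the earlier glucose time. With any 1 of 36 libraries left out the differences above stayed below 0 (-0.228 to -0.185 and -0.0661 to -0.0186). A shorter delay could leave the same-time value higher, so it is not tested here. Change that water and xylose cultures share at a given time would also raise same-time values. Glucose at 30 min also correlated less with arabinose at 60 than at 30 min, by -0.141 (-0.168 to -0.0901 with libraries left out). Unless such shared change is the source, this argues against arabinose at 60 min as glucose at 30 min delayed by the whole gap. Glucose at 15 min, however, correlated better with arabinose at 30 than at 15 min (0.511 and 0.218, a difference of 0.294 that stayed between 0.263 and 0.318), as a delay would give. The bound set beforehand left out this direction of comparison, so a delay over the first 30 min stays open. The same holds for any delay shorter than the gaps between sampling times.

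Called genes of at least 2-fold stood next to each other in 34 runs of 8 tags or more, 17 up and 17 down. These are summed over 6 comparisons, so a region such as CA_C1341 to CA_C1349 is counted more than once. In 18000 shuffled gene orders 2 had a run of 8, both for genes up with glucose at 60 min, where the longest real run had 65 tags. The bound set beforehand, no shuffled run of 8 at all, was too strict for a comparison with so many calls. All 34 runs were longer than the longest shuffled run of their own comparison and direction, so a chance order is argued against. The longest falling runs were CA_C1986 to CA_C2022 with glucose (36 tags, median -2.46) and CA_C1986 to CA_C2021 with arabinose (35 tags, median -2.81) at 60 min.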
